A study of Mus musculus with 11 samples.

How the data were processed

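The series holds 11 libraries of primary microglia from newborn C57BL/6 mice, 4 from microglia alone, 3 from microglia with untreated cortical neurons and 4 from microglia with neurons loaded with fluorescently labelled α-synuclein fibrils and washed. RNA was extracted with a micro-column kit and sequenced with a 3′ mRNA kit, per the labels' protocols. The labels do not state how microglia were separated from neurons, whether strand was used in counting, or whether duplicate reads were removed. The authors deposited a table of raw counts per gene symbol, in which counts of more than 6 digits carry 6 significant digits. The submitters' processing notes name STAR, Partek, DESeq2 and the mm10 build without versions. The authors also deposited a normalized table, treated here as a score: tested on the values, each is the count divided by 1 size factor per library and rounded, and between 99.9% and 100% of values in a library lay within 0.51 of that.

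Groups were taken from the treatment group given for each sample, and libraries were numbered within a group in the order of deposition. The table holds 16934 genes, of which 2828 had no count in any library and 11276 passed edgeR's filterByExpr and were tested. Raw counts were analysed in R 4.3.3 with edgeR 4.0.16, using TMM scaling and the quasi-likelihood test on all 11 libraries with group as the only term, two-sided, with Benjamini-Hochberg (BH) adjustment over genes and a threshold of 0.05. CPM values are counts scaled by TMM-adjusted library size, given as mean ± SD. The common biological coefficient of variation was 1.15. Log2 correlations between libraries had a median of 0.715 within groups and 0.707 between groups. Total counts ran from 8253070 to 16802451. A fold against a group with no count is given against a floor of 3 counts per library, and the floor covers counting error only, while the interval of a log2 fold change comes from edgeR's standard error and includes the spread between libraries.

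The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The 29 lists comprise 21 gene programmes and 8 sets of cell type markers. They were tested with limma 3.58.1's camera with a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Mitochondrially encoded, fibroblast and mural, endothelial, and neutrophil and monocyte genes had too few tested members, so BH adjustment was over the 25 testable lists and not over all 29 as first planned. Summed CPM were 9.58 in microglia alone, 2.85 with untreated and 4.39 with fibril-loaded neurons for fibroblast and mural genes, 63.8, 50.5 and 43.4 for endothelial genes, and 36.0, 73.5 and 56.9 for neutrophil and monocyte genes. No mitochondrially encoded gene was tested. Medians of a list are over members of at least 10 CPM in both groups. Sums of cell type lists were compared by two-sided exact permutation tests with BH adjustment over 8 lists and 3 comparisons.

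Genes were named by a rule. It takes, among called genes with CPM ranges that do not overlap, the 6 largest rises and 6 largest falls with at least 10 CPM in 1 group or more, and the same with at least 10 CPM in both groups. It adds up to 3 members with the smallest p per list, and always a fixed set that includes Trem2, Apoe, Cx3cr1, P2ry12, Tnf, Il1b, Tnfaip2 and Hmox1; some genes that the rule names are not reported here. Where none passed, the 3 with the smallest p were taken and said not to pass. Gene models without a proper symbol are counted and not named. Coordinates are from the RefSeq annotation of GRCm38.p6, whose chromosome coordinates are those of mm10; 16916 of the 16934 symbols matched.

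The code was tested on simulated data drawn from the real means, dispersions and library sizes with 200 changed genes. The changed genes were drawn only from those with a mean of at least 10 CPM. Between the co-cultures, 0% of 2-fold, 32% of 4-fold, 46% of 8-fold and 80% of 16-fold changes were found among 10692 genes tested, with 3 false calls. For untreated neurons against microglia alone 2%, 36%, 64% and 76% were found among 10662 genes tested, with 5 false calls. With fibril-loaded neurons against microglia alone 2%, 34%, 68% and 78% were found among 10678, with 1 false call. Each share is of the 50 genes changed at that fold, and pools abundant with less abundant genes. At 50 CPM or more, 14 of 17, 17 of 24 and 12 of 15 4-fold changes were found in these comparisons. In 5 simulations with nothing changed at most 1 gene was called. A shifted list was found in each comparison, and 1 of 19 unshifted lists was called between the co-cultures and 0 in the others. Genes were simulated independently, so this does not test the list p-values where members of a list are correlated. Alternatives were RLE scaling, no low-count filter, a mean CPM of at least 5, DESeq2 1.42.0, limma on the normalized table, the 2 groups compared only, genes with a mean of at least 10 CPM in microglia alone, the mean log2 CPM of a cell type list, the serial numbers in the titles as a block, the neuron list level as a covariate, and leaving out each library. Leaving out Rn45s, genes with a count in every library only, and leaving out the library with the fewest genes of each group were added after seeing the data. RLE scaling moved the median log2 fold change by no more than 0.006 from TMM. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.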

Results

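Gene expression was measured by 3′ mRNA sequencing in 11 libraries of primary mouse microglia, the resident immune cells of the brain. The series title places the work in a study of tunneling nanotubes, thin actin-based bridges between cells. Microglia cultured alone gave 4 libraries, microglia kept for 6 h with untreated primary cortical neurons gave 3, and microglia kept for 6 h with fibril-loaded neurons gave 4. The fibrils were of α-synuclein, the protein that aggregates in Parkinson's disease, and had been given to the neurons at 0.1 µM during the preceding 16 h. Total counts per library ran from 10700940 to 14541179 in microglia alone, from 10925771 to 16802451 with untreated neurons and from 8253070 to 14844071 with fibril-loaded neurons. Between 9157 and 11739 genes had at least 1 count in a library, and 6732 of the 16934 genes in the table had a count in every library. The labels do not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

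Microglial genes were abundant in every group. The pan-microglia and macrophage list of 20 genes, among them the growth factor receptor Csf1r and the complement gene C1qa, summed to 20890.4 ± 699 CPM (counts scaled to library size; SD, n = 4) in microglia alone. It summed to 25049 ± 1519 CPM (n = 3) with untreated neurons and 23134 ± 2554 CPM (n = 4) with fibril-loaded neurons. The neuron list of 32 genes was highest in the cultures without added neurons, at 1506 ± 92.9 CPM (n = 4), against 784 ± 126 CPM (n = 3) with untreated and 1008 ± 158 CPM (n = 4) with fibril-loaded neurons. Most of this sum was Basp1, a growth-cone protein gene, at means of 1264, 709 and 950.3 CPM. Against microglia alone, the neuron list sum differed by a log2 of -0.95 with untreated and -0.59 with fibril-loaded neurons. Each difference had a two-sided exact permutation p of 0.0286, the smallest the design allows, and 0.229 after Benjamini-Hochberg (BH) adjustment over 8 lists and 3 comparisons. At that smallest p a single list could not pass this adjustment, so its failure to pass decides nothing. Rn45s, the ribosomal RNA precursor, took 19.4 ± 4.45% of counts (n = 4) in microglia alone, 12.6 ± 2.69% (n = 3) with untreated and 12.8 ± 2.85% (n = 4) with fibril-loaded neurons. Its exact permutation p against microglia alone was 0.0857 with untreated and 0.0571 with fibril-loaded neurons, and 0.386 after BH adjustment in both.

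**Figure D1:**
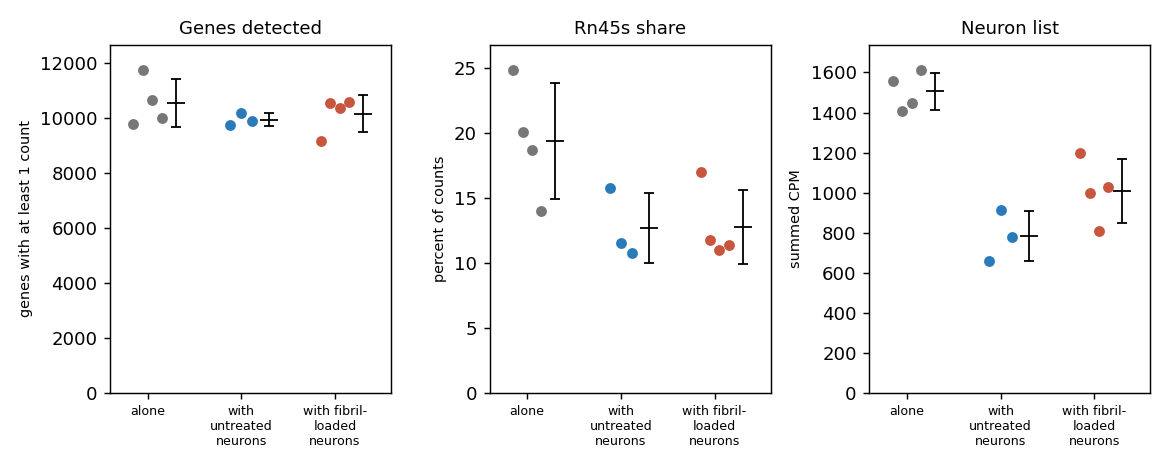
Genes with at least 1 count, percent of counts on Rn45s and summed CPM of the neuron list in libraries of microglia alone (grey), with untreated neurons (blue) and with fibril-loaded neurons (red); points are libraries and bars the mean ± SD. The neuron list lay between 1409.7 and 1610.3 CPM in microglia alone, above every co-culture library.

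Microglia with untreated neurons were set against microglia alone to show what 6 h beside neurons changed. Tgfbi, a secreted matrix protein gene, rose from 20.6 ± 8.38 CPM (n = 4) to 289 ± 107 CPM (n = 3), and Gpr84, a fatty acid receptor of activated myeloid cells, rose from 29.03 ± 28.4 to 359 ± 66.3 CPM. Genes of inflammatory activation rose as well: Acod1, the enzyme that makes itaconate, from 10.5 ± 7.12 to 311 ± 245 CPM, and the interferon-induced antiviral gene Rsad2 from 112 ± 55.6 to 737 ± 289.8 CPM. Cx3cr1, the receptor for neuronal fractalkine, rose from 602 ± 158 to 1880.1 ± 312 CPM. The tubulin gene Tubb2b fell from 635 ± 349 to 77.00 ± 32.99 CPM and the kinase gene Cdk18 from 159 ± 41.9 to 12.1 ± 4.56 CPM. The neuron list was lower too, and whether the genes that fell were expressed by microglia or by other cells in the cultures without neurons was not tested. In edgeR's quasi-likelihood test 52 genes were higher and 20 lower at a BH-adjusted p below 0.05, among 11276 tested. An unadjusted p below 0.05 was seen for 1164 genes, where 563.8 were expected with no effect. CPM ranges lay apart for 10.3% of genes, where chance gives 5.71%.

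Among genes of at least 10 CPM in both groups, the largest rises were those of Acod1 (log2 fold change 4.89, SE 0.74, edgeR BH-adjusted p = 0.00173), Pmepa1 (3.84, 0.60, 0.0024), Cxcl10 (3.81, 0.79, 0.026), Tgfbi (3.80, 0.39, 3.66e-05), Gpr84 (3.63, 0.53, 0.00153) and Cxcl14 (3.21, 0.37, 1.41e-04). Pmepa1 encodes a membrane protein that restrains TGF-beta signalling, and Cxcl10 and Cxcl14 encode chemokines. Some genes rose from a low level: Tgm2, a transglutaminase, from 7.89 ± 8.43 to 299 ± 67.6 CPM, Olfml3 from 1.21 ± 1.56 to 42.9 ± 26.5 CPM and Spsb1 from 0.245 ± 0.294 to 51.4 ± 33.6 CPM. The matrix protease gene Mmp19 and the calmodulin-binding protein gene Nrgn had no count in microglia alone. With untreated neurons they were 141-fold and 114-fold above a floor of 3 counts per library, which covers counting error only. The largest falls at 10 CPM or more in both groups were those of Cdk18 (log2 fold change -3.71, SE 0.50, edgeR BH-adjusted p = 8.55e-04), Tubb2b (-3.04, 0.43, 0.00153) and Hpgd, a prostaglandin-degrading enzyme (-2.84, 0.54, 0.0135). The Ras regulators Rasgrp3 (-2.14) and Rasa1 (-2.03) and the ubiquitin ligase gene Ttc3 (-1.97) followed. Dcx, the doublecortin gene of young neurons and a member of the neuron list, fell from 48.6 ± 22.4 to 0.0403 ± 0.0698 CPM, and Sco1, a copper chaperone gene, from 17.5 ± 13.9 to 0.0593 ± 0.103 CPM. Rgs7bp, Dkk2, Ankrd13b and Mgat5 had no count with untreated neurons, where the same floor lay 172-fold, 142-fold, 122-fold and 67.2-fold below microglia alone. Without library 1 of microglia alone the folds for Rgs7bp and Ankrd13b were 107-fold and 74.7-fold. Beside fibril-loaded neurons these 4 genes had counts, with means of 6.67, 1.04, 6.88 and 11.4 CPM. The calls of Mmp19, Nrgn, Rgs7bp, Dkk2, Ankrd13b and Mgat5 were lost on leaving out any single library, that of Sco1 in 6 of the 7 such fits, those of Dcx, Ttc3 and Il4ra in 5, of Cxcl10, Rasa1 and Ddx58 in 4, of Ifit3 in 3, of Hpgd and Olfml3 in 2 and of Rasgrp3 in 1. Reads of Tubb2b may be shared with other tubulin genes, so its level is uncertain. In mm10 coordinates the whole genes lie on chromosome 13 from 56609586 to 56639359 for Tgfbi, chromosome 13 from 56288643 to 56296811 for Cxcl14, chromosome 15 from 103308233 to 103310670 for Gpr84, chromosome 9 from 120048683 to 120068296 for Cx3cr1 and chromosome 1 from 132113547 to 132139698 for Cdk18.

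**Figure D2:**
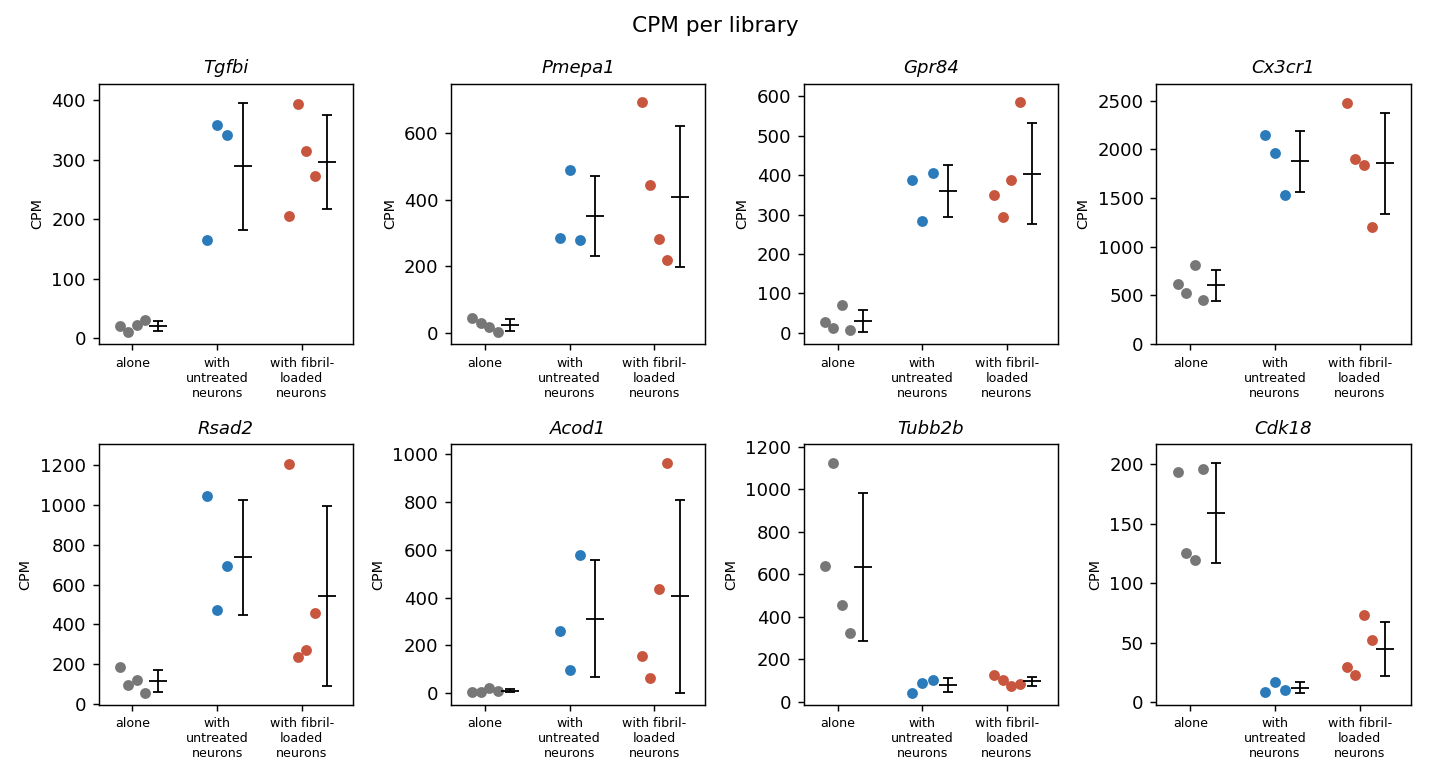
CPM of 8 genes, one panel per gene, in microglia alone (grey, n = 4), with untreated neurons (blue, n = 3) and with fibril-loaded neurons (red, n = 4); points are libraries and bars the mean ± SD. Tgfbi, Pmepa1, Gpr84, Cx3cr1, Rsad2 and Acod1 were higher and Tubb2b and Cdk18 lower in each co-culture library than in each library of microglia alone.

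The type I interferon response list rose with untreated neurons: 33 of 33 members were positive, with a median log2 fold change of 1.58 among the 26 of at least 10 CPM in both groups. Its camera BH-adjusted p was 8.03e-30 with a preset correlation, and the adjusted p was 0.0513 with an estimated correlation. Rsad2, Ifit3, the RNA sensor Ddx58, Oasl1 and Mx1 passed over all genes, the last pair being named after their values were seen, and 23 members passed adjusted over the list alone. Ifit3 rose from 72.7 ± 38.1 to 373 ± 196 CPM and Ddx58 from 30.7 ± 11.2 to 149 ± 107 CPM; reads of Ifit3, Oasl1 and Mx1 may be shared with near-identical genes. The NF-kB and inflammatory mediators list rose with 32 of 34 members positive and a median of 1.09 (camera BH-adjusted p = 6.68e-16, adjusted p = 0.111 with an estimated correlation). Acod1, Cxcl10, Sod2 and Tlr2 passed over all genes and 10 members passed adjusted over the list alone. Tlr2, a receptor for bacterial lipoproteins, rose from 60.96 ± 32.3 to 294 ± 123 CPM and the mitochondrial superoxide dismutase Sod2 from 124 ± 69.3 to 703 ± 401 CPM. The homeostatic microglia list rose with 17 of 21 members positive (camera BH-adjusted p = 8.84e-05, adjusted p = 0.111 with an estimated correlation). Cx3cr1 and Olfml3 passed over all genes, and 4 higher and 1 lower passed adjusted over the list alone. P2ry12, the purinergic receptor of resting microglia, was low at 9.70 ± 6.93 against 2.28 ± 3.99 CPM and did not pass.

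Smaller shifts upward were called in 5 further lists. Antigen presentation genes were positive in 12 of 18 (camera BH-adjusted p = 0.00126, adjusted p = 0.0513 with an estimated correlation). None passed over all genes, while H2-D1, H2-K1 and the peptide transporter Tap1, at 139 ± 40.8 against 51.3 ± 11.1 CPM, passed adjusted over the list alone; reads may be shared among H2 genes. Phagocytosis and complement genes were positive in 19 of 33 (camera BH-adjusted p = 0.00766, adjusted p = 0.111 with an estimated correlation), with Tlr2 over all genes and Tlr2, Fcgr1 and Itgb2 adjusted over the list alone. Hypoxia response genes were positive in 16 of 22 (camera BH-adjusted p = 0.00766, adjusted p = 0.111 with an estimated correlation). None passed over all genes, and the hexokinase Hk2, at 334 ± 48.2 against 144 ± 31.8 CPM, P4ha1 and Hif1a passed adjusted over the list alone. Oxidative stress genes were positive in 15 of 25 (camera BH-adjusted p = 0.00856, adjusted p = 0.307 with an estimated correlation), with Sod2 passing by both counts. Alternative activation genes were positive in 7 of 11 (camera BH-adjusted p = 0.025, adjusted p = 0.111 with an estimated correlation). Tgm2 and Il4ra, the interleukin-4 receptor, at 193 ± 44.4 against 57.6 ± 28.5 CPM, passed by both counts, and the median of -0.02 was opposite in sign to the test. On leaving out 1 library, the phagocytosis call was lost in 1, oxidative stress in 2 and alternative activation in 2 of 7 fits (limma camera BH-adjusted p up to 0.05995, 0.144 and 0.0701).

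Cell cycle genes fell with 33 of 36 members negative and a median log2 fold change of -0.52 (camera BH-adjusted p = 1.02e-04, adjusted p = 0.307 with an estimated correlation). None passed over all genes, and the replication helicase Mcm7, at 50.9 ± 29.3 against 191 ± 58.2 CPM, passed adjusted over the list alone. The neuron list fell with 13 of 17 members negative, Dcx over all genes and Dcx and Basp1 adjusted over the list alone (camera BH-adjusted p = 0.00126, adjusted p = 0.0513 with an estimated correlation). In the same libraries the neuron list sum and Rn45s share were lower, and the sums of astrocyte (log2 difference 1.14, exact permutation p = 0.0857), neutrophil and monocyte (1.11, 0.114) and pan-microglia genes (0.26, 0.0286) were higher, none passing BH adjustment. A single list sum could not pass it at the smallest possible p of 0.0286. The other 15 testable lists did not pass. Disease-associated microglia genes had a camera BH-adjusted p of 0.859, with Lpl, Ctsl and Lgals3 passing adjusted over the list alone. Its receptor Trem2 was at 651 ± 176 against 748 ± 168 CPM and the lipid carrier Apoe at 12769.6 ± 2833 against 13099 ± 1712 CPM. Camera BH-adjusted p was 0.792 for lysosome and autophagy genes, 0.216 for actin protrusion and tunneling nanotube factors, 0.231 for Parkinson's disease genes, 0.155 for oxidative phosphorylation, 0.936 for glycolysis, 0.212 for cholesterol biosynthesis and 0.92 for lipid efflux and fatty acid synthesis. It was 0.167 for the unfolded protein response, 0.592 for heat shock, 0.724 for immediate early genes, 0.0922 for astrocyte, 0.155 for oligodendrocyte, 0.724 for border-associated macrophage and 0.0629 for pan-microglia genes. Tnfaip2, which encodes the nanotube factor M-Sec, was at 1149 ± 779.7 against 464 ± 37.7 CPM (edgeR BH-adjusted p = 0.256). The cytokine genes Tnf (122 ± 67.9 against 56.7 ± 22.5 CPM) and Il1b (63.00 ± 69.5 against 9.62 ± 8.73 CPM) and the heme oxygenase gene Hmox1 (528 ± 369.96 against 204 ± 100.1 CPM) did not pass. Without the library with the fewest genes of each group, an alternative chosen after seeing the data, edgeR called 21 higher and 8 lower, and DESeq2 on all libraries called 171 higher and 316 lower. With the neuron list level as a covariate, which fully separates co-cultures from microglia alone, edgeR called 0 higher and 0 lower, with 387 genes at an unadjusted p below 0.05. On leaving out 1 library, 18 of the 32 called genes named by rule were lost.

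**Figure D3:**
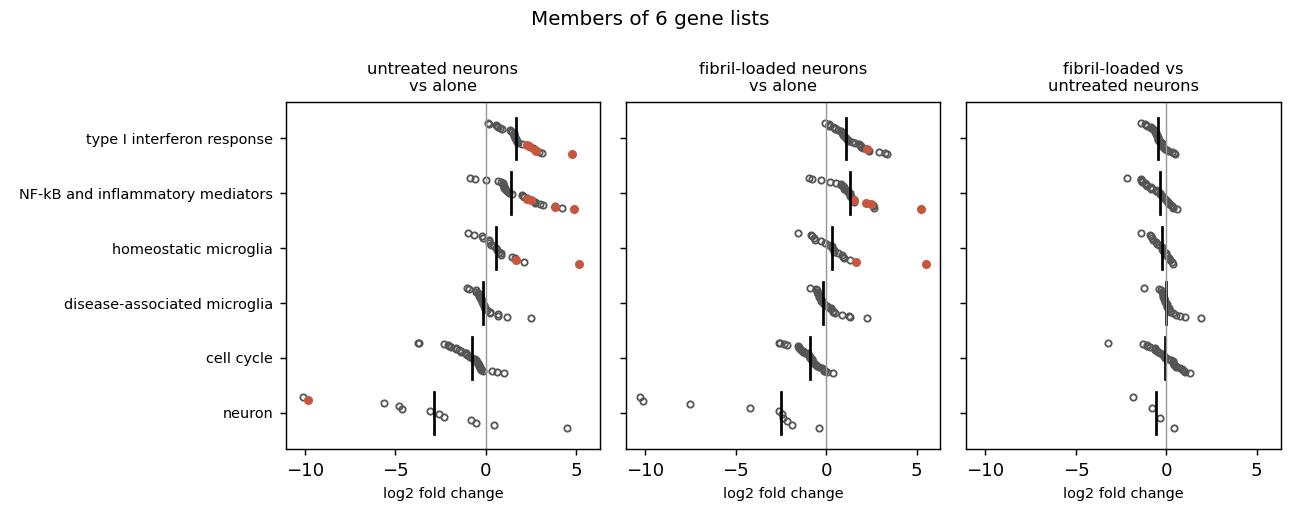
Log2 fold change of members of 6 gene lists with at least 10 CPM in at least 1 of the groups compared, for the 3 comparisons; circles are genes, filled red where edgeR's BH-adjusted p was below 0.05, and black bars the median of the members drawn. All 32 interferon members drawn were positive with untreated neurons against microglia alone, and 5 of 32 with fibril-loaded against untreated neurons.

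Microglia with fibril-loaded neurons were set against those with untreated neurons to show what the fibrils added. No gene passed: edgeR called 0 higher and 0 lower with a smallest BH-adjusted p of 0.903. Cx3cr1 was at 1858 ± 521 CPM (n = 4) with fibrils and 1880.1 ± 312 CPM (n = 3) without, and Tgfbi at 296 ± 79.2 and 289 ± 107 CPM. As a group, type I interferon response genes fell with fibrils, with 28 of 33 members negative and a median log2 fold change of -0.45. Its camera BH-adjusted p was 3.85e-05, and the adjusted p was 0.446 with an estimated correlation. Hypoxia response genes fell with 17 of 22 members negative and a median of -0.25 (camera BH-adjusted p = 0.0376, adjusted p = 0.446 with an estimated correlation).

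No member of these lists passed over all genes or adjusted over the list alone. Among interferon genes, Ddx58 was at 71.3 ± 42.1 with fibrils against 149 ± 107 CPM without, Herc6 at 28.8 ± 13.8 against 61.99 ± 20.02 CPM and Rtp4 at 182 ± 77.1 against 297 ± 96.9 CPM. Among hypoxia genes, the mitophagy receptor gene Bnip3 was at 19.4 ± 3.88 against 76.6 ± 33.4 CPM and the collagen hydroxylase P4ha1 at 84.6 ± 11.04 against 141 ± 17.2 CPM. The other 23 testable lists did not pass, with camera BH-adjusted p from 0.0832, for homeostatic microglia and for NF-kB genes, to 0.989. It was 0.88 for lysosome and autophagy, 0.989 for disease-associated microglia, 0.989 for actin protrusion and tunneling nanotube factors and 0.297 for Parkinson's disease genes. The formin Diaph1 was at 196 ± 62.4 against 101 ± 13.7 CPM, the actin bundler fascin, Fscn1, at 37.7 ± 18.2 against 85.4 ± 63.6 CPM and the Parkinson's disease gene Park7 at 61.9 ± 18.2 against 121 ± 32.8 CPM. The genes with the smallest p, none of which passed, included Sco1 at 19.2 ± 16.6 against 0.0593 ± 0.103 CPM, Mgat5 at 11.4 ± 7.84 CPM against no count, Cdk18 at 44.6 ± 22.7 against 12.1 ± 4.56 CPM, Tubb4b at 130.1 ± 43.1 against 58.7 ± 8.16 CPM and Ptchd1 at 61.8 ± 41.9 against 14.5 ± 8.84 CPM. On the lower side were Vps35l, a gene of the retriever sorting complex, at 44.6 ± 11.6 against 113 ± 24.6 CPM, folliculin, Flcn, at 37.9 ± 15.1 against 96.8 ± 4.84 CPM, Pgls at 22.9 ± 10.6 against 67.5 ± 32.7 CPM and Zfp687 with no count against 14.3 ± 12.6 CPM. Trem2 was at 759 ± 107 against 651 ± 176 CPM, Apoe at 10785 ± 2361 against 12769.6 ± 2833 CPM and P2ry12 at 6.88 ± 9.62 against 9.70 ± 6.93 CPM, none passing. Tnf was at 158 ± 102 against 122 ± 67.9 CPM, Il1b at 25.05 ± 34.98 against 63.00 ± 69.5 CPM, Tnfaip2 at 885 ± 491 against 1149 ± 779.7 CPM and Hmox1 at 566 ± 379 against 528 ± 369.96 CPM, none passing. In edgeR 445 genes had an unadjusted p below 0.05, where 563.8 were expected with no effect, and ranges lay apart for 4.68% of genes, where chance gives 5.71%. For the 2765 genes of at least 50 CPM in both groups, the unadjusted 95% interval of the log2 fold change had a median half-width of 0.78. After adjustment over genes, larger changes were also missed at this depth and spread. In simulated data for this comparison 0 of 18 2-fold changes at 50 CPM or more were found. DESeq2 called 156 genes higher and 46 lower, with 800 at an unadjusted p below 0.05, and 176 of its calls had no count in at least 3 of the 7 libraries; limma on the normalized values called 0, with 514 at an unadjusted p below 0.05. The interferon call was lost without library 1 with untreated neurons (limma camera BH-adjusted p = 0.0916), and the hypoxia call was lost in 4 of 7 fits that left out 1 library.

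Microglia with fibril-loaded neurons were set against microglia alone to show the joint difference, which in the same model is the sum of the other comparisons and shares their libraries. Cxcl14 rose from 20.4 ± 6.05 CPM (n = 4) to 333 ± 73.7 CPM (n = 4), Tgfbi from 20.6 ± 8.38 to 296 ± 79.2 CPM, Gpr84 from 29.03 ± 28.4 to 404 ± 127 CPM and Tgm2 from 7.89 ± 8.43 to 367 ± 44.1 CPM. Cx3cr1 rose from 602 ± 158 to 1858 ± 521 CPM. Tubb2b fell from 635 ± 349 to 95.7 ± 22.7 CPM and Hpgd from 222 ± 118 to 30.5 ± 22.4 CPM. Here too it was not tested whether the genes that fell were expressed by microglia or by other cells. In edgeR 30 genes were higher and 6 lower at a BH-adjusted p below 0.05, and 918 had an unadjusted p below 0.05 where 563.8 were expected with no effect. CPM ranges lay apart for 5.62% of genes, where chance gives 2.86%.

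The largest rises at 10 CPM or more in both groups were those of Acod1 (log2 fold change 5.26, SE 0.73, edgeR BH-adjusted p = 6.94e-04), Pmepa1 (4.06, 0.59, 9.48e-04), Cxcl14 (4.03, 0.38, 5.92e-06), Tgfbi (3.84, 0.38, 9.70e-06), Gpr84 (3.80, 0.52, 6.94e-04) and the ubiquitin ligase gene Neurl3 (2.71, 0.41, 0.00169). Olfml3 rose from 1.21 ± 1.56 to 55.5 ± 23.4 CPM and Spsb1 from 0.245 ± 0.294 to 25.5 ± 15.9 CPM. The genes that fell were Tubb2b (log2 fold change -2.73, SE 0.38, edgeR BH-adjusted p = 6.94e-04), Hpgd (-2.86, 0.48, 0.00563), Rasgrp3 (-1.70, 0.35, 0.0314), the fatty acid desaturase Scd2 (-1.53, 0.30, 0.0193), Tox2 and Igfbpl1. Tox2 was at 7.65 ± 1.72 against 193 ± 123 CPM. Igfbpl1 had no count beside fibril-loaded neurons, where the floor of 3 counts lay 138-fold below microglia alone, or 53.3-fold without library 2 of microglia alone.

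The type I interferon response list rose with 32 of 33 members positive and a median log2 fold change of 1.00 (camera BH-adjusted p = 2.91e-19, adjusted p = 0.178 with an estimated correlation). Rsad2, at 544 ± 454 against 112 ± 55.6 CPM, passed over all genes and 13 members passed adjusted over the list alone. The NF-kB list rose with 29 of 34 members positive and a median of 1.17 (camera BH-adjusted p = 9.23e-13, adjusted p = 0.198 with an estimated correlation). Acod1, Sod2, Tlr2 and the inhibitor gene Nfkbia, named after its values were seen, passed over all genes and 7 members passed adjusted over the list alone. Homeostatic microglia genes were positive in 13 of 21 (camera BH-adjusted p = 0.0161, adjusted p = 0.2997 with an estimated correlation), with Cx3cr1 and Olfml3 passing over all genes and adjusted over the list alone. Oxidative stress genes were positive in 17 of 25 (camera BH-adjusted p = 0.00192, adjusted p = 0.261 with an estimated correlation), with Sod2 over all genes and Sod2, Gpx1, Txnrd1 and Hmox1 adjusted over the list alone. Antigen presentation genes were positive in 11 of 18 with none passing by either count, phagocytosis and complement genes in 17 of 33 with Tlr2 over all genes and Tlr2 and Itgb2 adjusted over the list alone. Alternative activation genes were positive in 6 of 11, with Tgm2 over all genes and Tgm2, Il4ra and the mannose receptor Mrc1, which was lower, adjusted over the list alone. These 3 lists each had a camera BH-adjusted p of 0.0367 upward, an adjusted p of 0.198 with an estimated correlation, and medians of -0.05, -0.05 and -0.65, opposite in sign to the test.

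Cell cycle genes fell with 34 of 36 members negative and a median log2 fold change of -0.75 (camera BH-adjusted p = 1.65e-06, adjusted p = 0.298 with an estimated correlation). None passed over all genes, and Mcm7 at 66.3 ± 36.7 against 191 ± 58.2 CPM and the microtubule regulator Stmn1 at 107 ± 52.6 against 256 ± 80.5 CPM passed adjusted over the list alone. The neuron list fell with 15 of 17 members negative, none over all genes and Dcx, Stmn4 and Celf4 adjusted over the list alone (limma camera BH-adjusted p = 5.31e-05). Of the list calls in the 3 comparisons, this was the one that held with an estimated correlation (adjusted p = 0.034). The neuron list sum and Rn45s share were lower in these co-cultures too, and the astrocyte, neutrophil and monocyte, and pan-microglia sums higher by a log2 of 0.67, 0.79 and 0.14, none passing BH adjustment. Here too a single list sum could not pass it at the smallest possible exact permutation p of 0.0286. The other 16 testable lists did not pass, with camera BH-adjusted p of 0.224 for actin protrusion and tunneling nanotube factors, 0.564 for lysosome and autophagy, 0.781 for disease-associated microglia, 0.564 for hypoxia and 0.868 for Parkinson's disease genes. Trem2 at 759 ± 107 against 748 ± 168 CPM, Apoe at 10785 ± 2361 against 13099 ± 1712 CPM, Tnf, Il1b, P2ry12, Tnfaip2 and Hmox1 did not pass. DESeq2 called 136 higher and 127 lower, of which 35 were shared with edgeR, and with the neuron list level as a covariate edgeR called 4 higher and 0 lower. Of the 20 called genes named by rule, Igfbpl1, Olfml3, Rasgrp3, Rsad2, Scd2 and Tox2 were lost on leaving out 1 or more single libraries, as were the list calls for homeostatic (3 of 8 fits), antigen presentation (4), phagocytosis (4), oxidative stress (1) and alternative activation genes (3). In these fits Tox2 held only without library 4 and Igfbpl1 only without library 1 of microglia alone. Rsad2 was lost without library 1 with fibril-loaded neurons or library 2, 3 or 4 of microglia alone. Tox2 was also lost with DESeq2, with limma on the normalized values and at a mean CPM of at least 5.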

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

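The splits of the libraries for edgeR and both uses of the neuron list without Basp1 were tests chosen after the result was seen, and the remaining tests here before it. A library was singled out where its gap to the nearest other library of its group of 4 exceeded Dixon's 95% critical share of the group's range. This held for 12 of 196 groups of values, where chance gives about 9.8. Library 1 with fibril-loaded neurons had the fewest genes detected, 9157 against 10378 to 10593 in the others of its group, and the highest Rn45s share, 17.01% against 10.97% to 11.7%. In that library the interferon genes Ifit3, at 578 CPM against 167 to 187, and Mx1, at 158 CPM against 23.7 to 31.2, were highest, as was Map2, a neuronal microtubule gene, at 16.9 CPM against 0.332 to 3.04. The group with untreated neurons was too small for this rule. Its library 1, whose title carries the preceding serial number, also had the highest Ifit3 of its group, at 598 CPM against 235 and 287. The high Ifit3 was thus not particular to 1 fibril-loaded library. Library 2 with fibril-loaded neurons had the highest Plin2, a lipid droplet gene, at 2459 CPM against 1708 to 1829.8. Library 3 with fibril-loaded neurons had the highest Ttc3, at 95.7 CPM against 55.1 to 58.1. Library 1 of microglia alone had the lowest border-associated macrophage list sum, 1423 CPM against 1863 to 1915. Library 2 of microglia alone had Camk2a, a neuronal kinase gene, at 1.88 CPM where the others had none. Library 3 of microglia alone had the highest P2ry12, at 8.24 CPM against 0 to 0.893, and Tlr2, at 109 CPM against 40.02 to 50.5. Library 4 of microglia alone had the lowest Kif11, a mitotic motor gene, at 6.52 CPM against 30.5 to 32.7.

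DESeq2 called 202 genes between the co-cultures where edgeR called 0. In 7 of the 35 splits of these libraries DESeq2 called as many, with 303 in the highest other split, so chance cannot be excluded. The median of the other splits was 171.5 calls, as transcripts missed at random in single libraries would give. Any other source of calls unrelated to the groups would give the same, so the splits do not single out missed transcripts. Of the 202 called genes, 3 had a mean of at least 50 CPM. For edgeR's 0 calls (445 genes at an unadjusted p below 0.05) the splits decide nothing, since all 35 must call at least 0; the highest other called 2. An effect of the fibrils on some of these genes stays open.

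Genes called between microglia with untreated neurons and microglia alone numbered 72 in edgeR and 20 in the highest of the other splits. Thus 1 of 35 splits called as many, the smallest share that 35 splits allow. This argues against chance as the source of so many calls but cannot exclude it, and it does not cover single genes. For fibril-loaded neurons against microglia alone, 36 genes were called, 1 in the highest of the other splits, and 1 of 35 splits called as many.

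RNA of neurons carried into the co-culture libraries was weighed as a source of the 52 genes higher with untreated neurons. The neuron list without Basp1 summed to no more than 82.0 CPM in any library with untreated neurons, with Snap25, Stmn2, Syp and Thy1 at 0 and Tubb3 at 0.747 CPM. For 21 of the 52 genes the step from the highest library alone to the lowest with neurons was larger than that whole sum. Among them were Tgfbi, Gpr84, Rsad2, Tgm2 and Cx3cr1. This speaks against neuronal RNA for the 21 only if Basp1 is left out, a choice made after the result was seen. With Basp1 the list summed to 660 to 913 CPM with untreated neurons, and the largest step was 722 CPM, for Cx3cr1. The list also sets no upper limit for other neuronal genes, so neuronal RNA is not excluded for the 21. For the other 31 it stays open: the sum differed by a log2 of -1.65, lower with neurons, a reading first taken as an exclusion and changed after the value was known, since genes such as Dcx were high in microglia alone, while Camk2a (0.471 CPM alone against 10.6), Nefl (0.155 against 6.59) and the called gene Nrgn (0 against 29.9) were higher with untreated neurons. A response of microglia to neurons, and differences in handling between culture with and without neurons, stay open for all 52. RNA of other cells in the neuron cultures was not weighed and stays open too. The astrocyte sum was higher with untreated neurons by a log2 of 1.14 (exact permutation p = 0.0857). Genes here outside the naming rule were chosen after their values were seen.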

How the results depend on the processing

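Leaving out Rn45s, genes without a count in every library and the libraries with fewest genes were tests chosen after the result was seen. RLE scaling changed no count. Of the 32 called genes named by rule with untreated neurons against alone, 12 passed in every setting that tested them except the neuron covariate and 32 were lost with it; with fibril-loaded neurons against alone, 13 of 20 passed and 16 were lost. None of these reversed. The neuron covariate fully separates co-cultures from microglia alone, so it takes up much of the difference between the groups. A loss of calls with it therefore does not tell neuronal RNA from co-culture itself. Without a low-count filter edgeR called 5 genes higher between the co-cultures, and against alone 155 higher and 79 lower with untreated and 114 and 50 with fibril-loaded neurons. A mean CPM of at least 5 left 12 and 3 lower against alone. DESeq2 called 156 higher and 46 lower between the co-cultures, and 171 and 316, and 136 and 127, against alone. The neuron covariate left 0 higher and 0 lower with untreated neurons, with 387 genes at an unadjusted p below 0.05 in edgeR, and 4 and 0 with fibril-loaded neurons against alone. With it, lists called were 1 higher and 1 lower in each comparison, the interferon list kept its calls (limma camera BH-adjusted p = 4.12e-12 and 7.37e-12 against alone), and the NF-kB list with untreated neurons reversed in direction with a camera BH-adjusted p of 0.969 (range over its alternatives 4.82e-22 to 0.969). With an estimated correlation 0 lists were higher in any comparison, and 0 lower between the co-cultures, 0 with untreated and 1 with fibril-loaded neurons. With fry 0, 1 and 1 were lower, and 0, 6 and 0 higher. Without the library with the fewest genes of each group, 1 gene was higher and 1 list lower between the co-cultures, and 21 genes higher and 8 lower with untreated neurons against alone. The cause was not tested.

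Serial numbers in titles form 4 sets. Deviations of libraries of the same set had a median correlation of 0.0333 and none of 10 pairs over 0.1. Pairs of different sets had a median of -0.0113. Same-set pairs of a fibril-loaded and an untreated co-culture had 0.0578, 0.0415 and 0.0434, and the highest other pair of these groups 0.0186. Same-set pairs with a library of microglia alone ran from -0.0257 to 0.0408. A weak pairing by set is thus not excluded, and the main test did not include it. With the serial set as a block 73 genes were higher and 22 lower with untreated neurons against alone, and 53 and 13 with fibril-loaded neurons. The calls of Dkk2, Mgat5, Sco1 and Ttc3 with untreated neurons against alone were lost with this block.

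Leaving out each library gave 0 to 1 genes higher and 0 to 1 lower between the co-cultures, with 0 to 0 lists higher and 0 to 4 lower. There, 1 gene was higher without library 1 or 2 with untreated neurons and 1 lower without library 4 with fibril-loaded neurons; lists lower were 1 without library 1 and 4 without library 3 or 4 with fibril-loaded neurons, and 0 without library 1 and 1 without library 3 with untreated neurons. With untreated neurons against alone, 25 to 62 genes were higher and 4 to 21 lower, with 7 to 10 lists higher and 2 to 3 lower. The higher and lower counts were 28 and 4, 25 and 11, and 30 and 11 without library 1, 2 or 4 of microglia alone, and 33 and 13, and 30 and 7, without library 1 or 3 with untreated neurons. With fibril-loaded neurons against alone, 21 to 39 genes were higher and 2 to 5 lower, with 3 to 8 lists higher and 2 lower. Lower genes were 3, 2 and 3 without library 1, 2 or 3 of microglia alone and 3 without library 3 or 4 with fibril-loaded neurons, and lists higher were 3 without library 2 of either group. The hypoxia list between the co-cultures was lost without library 1 with fibril-loaded or any library with untreated neurons (limma camera BH-adjusted p up to 0.116). With untreated neurons against alone, calls were lost for phagocytosis without library 2 of microglia alone (0.05995), oxidative stress without that or library 3 with untreated neurons (0.144), and alternative activation without library 3 of microglia alone or 1 with untreated neurons (0.0701). With fibril-loaded neurons against alone, homeostatic (up to 0.0981), antigen presentation (0.108), phagocytosis (0.204) and oxidative stress lists (0.0755) were lost without library 2 of microglia alone. Without library 2 with fibril-loaded neurons these but oxidative stress, and alternative activation (up to 0.206), were lost. Further losses were homeostatic and phagocytosis without library 3 and antigen presentation and alternative activation without library 1 with fibril-loaded neurons, and antigen presentation and phagocytosis without library 4 and alternative activation without library 3 of microglia alone. Depth and spread set limits: 0% to 2% of simulated 2-fold changes were found.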

Other observations

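The lists of TGF-beta targets and of young-neuron genes were chosen after the called genes were seen, and the tests of them before their own results were seen. Border-associated macrophage genes went in both directions beside neurons. Pf4, a platelet chemokine gene that these macrophages also express, rose from 241 ± 70.9 to 606 ± 65.1 CPM with untreated neurons (edgeR BH-adjusted p = 0.0488), a call lost on leaving out any single library. The transcription factor gene Maf was at 174 ± 24.5 with untreated and 159 ± 36.3 with fibril-loaded neurons against 331 ± 54.9 CPM in microglia alone, and passed adjusted over the list alone in both comparisons. The mannose receptor gene Mrc1 was at 194 ± 72.8 and 157 ± 44.7 against 317 ± 26.1 CPM. In the glycolysis list, which was not called, the hexokinase gene Hk2 was at 334 ± 48.2 and 288 ± 81.8 against 144 ± 31.8 CPM while the next enzyme of the pathway, Gpi1, was at 157 ± 24.6 and 143 ± 26.1 against 274 ± 79.7 CPM. The lipid droplet gene Plin2 was at 1318 ± 597 with untreated and 1948 ± 344 with fibril-loaded neurons against 876 ± 171 CPM in microglia alone, and passed adjusted over the list alone in the latter comparison. Astrocyte genes were low, the list summing to 145 ± 112 CPM with untreated neurons, 113 ± 92.9 CPM with fibril-loaded neurons and 56.9 ± 18.8 CPM in microglia alone, with an exact permutation p of 0.0857 for untreated neurons against microglia alone.

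Tgfbi, Pmepa1 and Tgm2, which rose with untreated neurons, are known targets of TGF-beta, so TGF-beta signalling may be raised in microglia beside neurons. A list of 26 further targets that left out the called genes, 22 of them tested, was expected to be higher at a camera p below 0.05. That expectation was not met: the camera p was 0.0845 with a preset correlation (0.127 after BH adjustment over 6 tests), with 15 of 22 members positive. The prediction said such a p would speak against the explanation, and reading it as undecided was set afterwards, because a list that leaves out the called genes excludes nothing. With fibril-loaded neurons the same list had a camera p of 0.00223 (0.00445 after BH adjustment, and a p of 0.0582 with an estimated correlation), and the question stays open.

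The neuron list was lower in both co-cultures, and young neurons in the cultures of microglia alone may account for it. A list of young-neuron genes outside the neuron list, of which 26 were tested, was lower in both comparisons, with 23 and 21 members negative and the larger camera p at 6.79e-06 (p of 0.0723 and 0.0549 with an estimated correlation). Marcksl1, the most abundant of these genes in both co-cultures, went the other way, at 149 ± 60.2 CPM in microglia alone against 385 ± 172 with untreated and 306 ± 168 CPM with fibril-loaded neurons, while Tubb2a was at 181 ± 49.5 against 118 ± 46.96 and 121 ± 51.1 CPM and Sox4 at 158 ± 75.6 against 87.4 ± 42.4 and 109 ± 55.3 CPM. Sox11, a transcription factor gene of young neurons, was at 67.03 ± 29.9 CPM in microglia alone against 1.13 ± 1.75 and 3.65 ± 4.19 CPM, and Nnat at 50.1 ± 27.4 against 3.52 ± 2.94 and 8.07 ± 6.83 CPM, all 5 named after their values were seen. Over its 17 tested members the neuron list had a median log2 fold change of -2.30 with untreated and -2.16 with fibril-loaded neurons. Both lay at percentile 0 of 10000 random lists matched on mean CPM, which had medians of -0.10 and -0.093. Depth of the libraries, where it acts on genes by their level, is thus argued against. The percentile takes genes as independent, and other effects of depth were not tested. Expression of these genes by other cells of the glial culture, or by microglia, was not tested, and 4 of the 26 genes were at 50 CPM or more in every group.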
